A study of Equus caballus with 22 samples.

How the data were processed

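Endometrial biopsies of warmblood mares had been collected at day 8 or day 12 of early pregnancy, after the embryo had been recovered, and at the matching stage without pregnancy. RNA had been extracted with Trizol, copied to Cy3-labelled cRNA with a 1-colour kit and hybridised to Agilent horse arrays, per the labels' protocols. The extraction protocol gives RNA integrity numbers of 8.3 to 9.2 and speaks of 12 samples, so it is open whether the range also covers the day 8 samples. The 22 arrays comprised 6 mares with a pregnant and a control sample at day 12 and 5 mares with both at day 8.

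The scanner output of each array holds spot intensities on a linear scale, which the authors made with Agilent Feature Extraction, version 10.5.1.1 per the submitters' processing notes. Per the file headers this version was used for the day 12 arrays and version 10.7.3.1 for the day 8 arrays. The processed intensity of a spot is background-subtracted and spatially detrended, with small values replaced by a positive surrogate, per the file headers, and is not scaled between arrays. The authors' deposited value table holds processed values of the same arrays that were read as log2, because they rose with the log2 scanner intensity with a correlation of 0.986 to 0.997 and a slope of 0.811 to 0.908 over features. It fills 36519 of the 43803 features that are not controls at day 12 and 36418 at day 8, so different features were filled at each day. Its column medians for the pregnant and control array were 8.68 and 8.59 in mare 1 at day 12, 8.63 and 8.57 in mare 2, 8.74 and 8.80 in mare 3, 7.57 and 7.53 in mare 4, 8.83 and 8.79 in mare 5, and 7.62 and 7.51 in mare 6. At day 8 they were 7.47 and 7.51 in mare 1, 8.37 and 8.36 in mare 2, 8.53 and 8.64 in mare 4, 8.40 and 8.38 in mare 5, and 7.97 and 7.99 in mare 6. The centring and normalisation behind that table are not given in the sources used here, and it served as an alternative only.

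For the main analysis the log2 processed intensity was taken minus the 75th percentile of all non-control spots of the array. Spots marked as non-uniform outliers, 3 to 152 per array, were left out, and spots of the same probe were averaged, giving 43603 probes. Probes had to be well above background on at least 5 of the 22 arrays, which 38461 were. The share of spots well above background ranged from 74.2% to 92.9% per array, the 75th percentile of the intensity from 577 to 1863 units, and the coefficient of variation of replicated probes from 5.90% to 13.1%. No spot was saturated. The precision of the comparisons is limited by the number of arrays. Where a probe was well above background on no array of the dimmer group, a fold is given only as a lower bound, and where it was on some of them the number of arrays is given. The bound sets the mean of the brighter group against the dimmer group's mean of, per array, the lowest normalised signal well above background or the probe's own value, whichever was higher.

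Probes carry accessions but no symbols. A table of RefSeq genes of the horse assembly TB-T2T, matched on RefSeq accessions without version, gave 1 symbol to 1394 probes (675 genes), several to 1 probe and none to 42208, of which 32620 carry an Ensembl transcript name. The 2 versions of the array annotation in the scanner output give different accessions for 3820 features. Genes without such a match are therefore counted but not named, and no coordinates are printed because the builds differ.

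Changes were tested per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). All 22 arrays entered 1 fit with each mare within a day as a fixed block and a pregnancy effect per day, and the difference between the 2 effects was tested in the same fit. Control samples of the 2 days were compared in a fit of the 11 control arrays without covariates. A Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. The pairing comes from the labels, which give every mare a pregnant and a control sample. As a check, the deviations of same-mare arrays from their group means correlated at 0.289 to 0.725 at day 12 and at 0.321 to 0.817 at day 8 over 31038 probes, and in all 11 pairs the pregnant array correlated best with the control array of its own mare. Both arrays of every pair lay on 1 slide. The 4 slides and 3 scan days of day 12 held no day 8 array, and day 8 had 3 slides and 2 scan days of its own.

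Gene lists were tested with camera, with a preset correlation of 0.01, over 604 named genes as the background, each gene standing by its probe with the highest mean signal. Of 30 lists, 9 had the 5 measured members that a test required. They were interferon response genes, growth factors and their binding proteins, secreted proteins of uterine fluid, prostaglandin synthesis and signalling, steroid metabolism, extracellular matrix and its remodelling, calcium and ion transport, chemokines with cytokines and their receptors, and markers of T and NK lymphocytes. Adjustment was over these 9 lists within a day, and the lists were tested again with an estimated correlation and with fry. List members named beside their list carry the value of the probe used in the list test.

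The designs, lists, alternatives and the rule for naming genes were fixed before the data were examined. Among probes with 1 symbol, the probe with the smallest p stood for a gene. At day 12 the 15 largest rises and 10 largest falls were to be named among probes past the threshold that moved the same way in all 6 mares. At day 8 the rule took 10 of each with all 5 mares, or the 5 smallest p in a direction with fewer than 5 past the threshold, of which 1 lower gene is not reported here. For the difference between days it took the 5 largest in each direction, and for the control samples the 8 largest rises and 8 largest falls among probes whose groups do not overlap. Up to 4 members of each list with the smallest p were added. From a fixed set of genes to be named whatever their values, ESR1, PTGS2 and PTGFR carried a symbol and stand by their brightest probe. Of accessions without a symbol, the 2 that rose most and the 2 that fell most at day 12 are printed.

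The procedure was tested on simulated data over 38103 probes. For day 12 it recovered 44.8% of 1.5-fold, 70.1% of 2-fold and 98.5% of 4-fold changes, with 13 false calls among 155. For day 8 the shares were 31.3%, 65.7% and 97.0%, with 7 false calls among 136. For the difference between days they were 17.9%, 46.3% and 80.3%, with 4 among 100. For the control samples of the 2 days they were 0%, 28.4% and 69.7%, with 5 among 70. The simulated control arrays held no differences between slides, scan days or software, so these figures do not cover such effects. A simulated shift of the interferon list by 0.50 log2 was found over 604 genes, and no list was called without a shift. The simulated noise was independent between genes, so this does not test how correlated genes affect the list calls.

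Alternatives were normexp background correction with an offset of 50, quantile normalisation, no filter on dim probes or a filter on all 22 arrays, marked spots kept, the authors' value table, a trended robust variance prior, no mare block, slide as a block, the arrays of 1 day alone, each mare left out, and, for lists, other correlations, tests and probe averaging. Leaving a mare out removed the arrays of its number on every day on which it has them. Normexp was planned on mean spot signals and was run on median spot signals, which the scanner output holds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.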

Results

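Gene expression was measured in the endometrium, the lining of the uterus, of mares in early pregnancy. At day 12, 6 mares each gave a pregnant and a control sample. At day 8, 5 mares did. The study asked which transcripts differ with pregnancy at each of these days, and the design also allows the pregnancy effects of the 2 days and the control samples of the 2 days to be compared. Levels are log2 intensities relative to the 75th percentile of the array, and changes are pregnant over control within a mare unless stated otherwise.

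At day 12, 7 named genes rose and 1 fell in pregnant endometrium. CHGA, which encodes the granule protein chromogranin A of endocrine cells, rose by 2.79 ± 0.48 log2 (SE, n = 6 mares, adjusted p = 0.0449), and was well above background on 6 of 6 pregnant and 5 of 6 control arrays. CALCA, the gene of calcitonin and its related peptide, rose by 2.23 ± 0.37 (adjusted p = 0.0390) from control values mostly at background, and GM2A, a lysosomal activator of ganglioside breakdown, by 2.10 ± 0.22 (4.28-fold, adjusted p = 0.0027), from a level of 0.63 ± 0.50 in control to 2.73 ± 0.79 in pregnant samples (SD, n = 6 each). CDH13, a cadherin anchored to the membrane by a lipid, rose by 1.06 ± 0.16 (2.08-fold, adjusted p = 0.0185). PTGDS, a prostaglandin D synthase, was the named gene that fell, by 0.39 ± 0.07 (adjusted p = 0.0407).

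Smaller rises were found for RND3 (0.77 ± 0.12, adjusted p = 0.0327), ANGPTL2, a secreted angiopoietin-like protein (0.73 ± 0.10, adjusted p = 0.0153), and ABCC1, an export transporter (0.68 ± 0.12, adjusted p = 0.0474). These 8 genes, 7 higher and 1 lower, were the named genes past the threshold among 609 tested, and each moved the same way in 6 of 6 mares. The rise of CHGA ranged from 0.25 to 4.87 log2 between mares, whereas that of RND3 ranged from 0.59 to 0.90. For CHGA, 1 of 5 probes passed, and the 5 lay between 2.71 and 2.83. The 2 probes of CALCA, which carry different accessions, gave 2.23 and 0.14, and the one that passed was well above background on 4 of 6 pregnant and 1 of 6 control arrays. ABCC1 and PTGDS passed with 1 of their 2 probes each. With 1 mare left out GM2A passed in 6 of 6 fits, ANGPTL2 in 3, CHGA and ABCC1 in 2 each, and CALCA, CDH13, RND3 and PTGDS in 1 each.

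**Figure D1:**
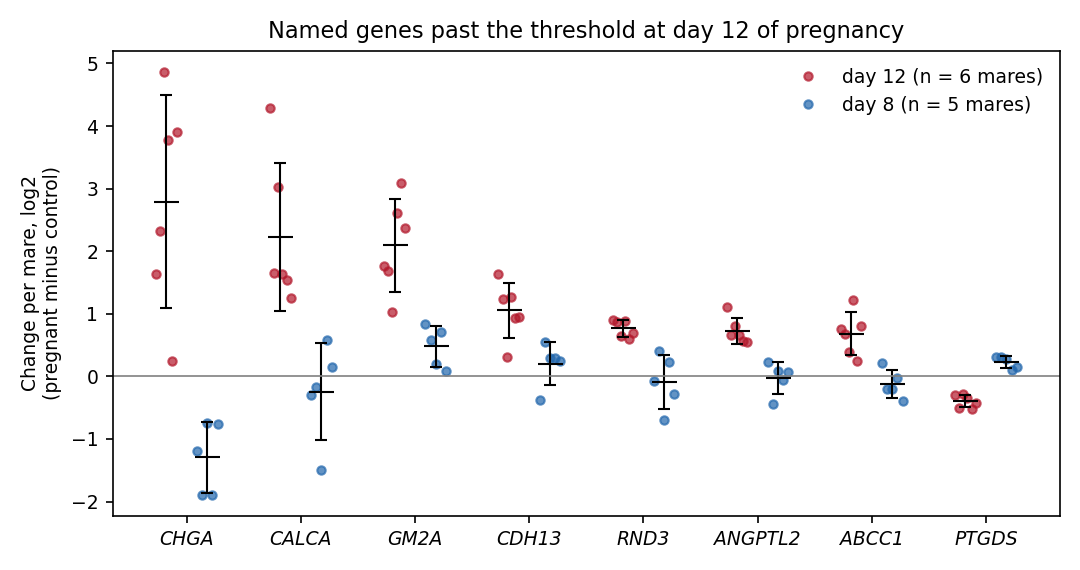
Change per mare (log2, pregnant minus control, vertical axis) of the 8 named genes past the threshold at day 12 (horizontal axis), in the 6 mares of day 12 (red) and the 5 mares of day 8 (blue). Points are mares, bars the mean ± SD. At day 12 all points of 7 genes lie above 0 and those of PTGDS below it, while CALCA at day 8 was not well above background on any array.

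Most transcripts that changed at day 12 carry no symbol here. In all, 102 of 38461 probes passed the threshold, 81 higher and 21 lower in pregnancy, and 100 of the 102 moved the same way in all 6 mares. They carry 62 accessions, of which 51 rose and 11 fell, and 70 of the probes changed more than 2-fold. The transcript DN508408 rose by 6.72 ± 0.57 log2 (SE, adjusted p = 0.00057, all 5 probes past the threshold, n = 6 mares). ENSECAT00000015626 rose by 5.23 ± 0.29 (adjusted p = 3.5e-05, all 5 probes) and was well above background on 6 of 6 pregnant and 1 of 6 control arrays, so that the size of its rise is set against values mostly at background. DN510735 fell by 2.32 ± 0.31 on the log2 scale with all 10 probes past the threshold, and ENSECAT00000022839 fell by 2.27 ± 0.19 with 1 of 2 probes, well above background on 3 of 6 pregnant and 6 of 6 control arrays.

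The count at day 12 depended on which mare was left out. Leaving out a mare removed the arrays of its number on both days, except for mare 3, which has arrays of day 12 only. Without mare 3, whose changes correlated at -0.154 with the mean of the other mares across 31038 probes, 977 probes passed, among them all 102, whereas without mare 1 it was 22, without mare 2 it was 31, without mare 6 it was 28 and without mare 4 it was 47. With the day 12 arrays fitted alone 9 probes passed, 9 higher and 0 lower. Without the mare block 41 passed, with slide as the block 89, with a filter on all 22 arrays 218, with the trended robust prior 287 and 303 with the authors' value table. All 102 moved the same way on each of the 4 slides, which largely restates how they were selected, since the fit used these same pairs. With normexp background correction 13 rose and 0 fell, against 81 and 21.

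Of the 9 gene lists tested at day 12, 3 rose, although no member of any list passed over all probes through its list probe. All 9 measured interferon response genes, which cells switch on as a defence against viruses, were higher, with a median of 0.31 log2 (adjusted p = 0.00582). With an estimated correlation between genes the adjusted p = 0.356, and with fry it was 0.122. IFI27 was higher by 0.49 ± 0.16 (SE, n = 6 mares), the RNA-dependent kinase gene EIF2AK2 by 0.45 ± 0.17, OAS2, which makes oligoadenylates, by 0.40 ± 0.19 and MX1, an antiviral GTPase, by 0.31 ± 0.16, and none of the 9 passed adjusted over the list alone. The median of the list was above 0 in 5 of 6 mares and -0.20 in mare 3, and on the 4 slides it was 0.06, 0.42, 0.19 and 0.35.

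**Figure D2:**
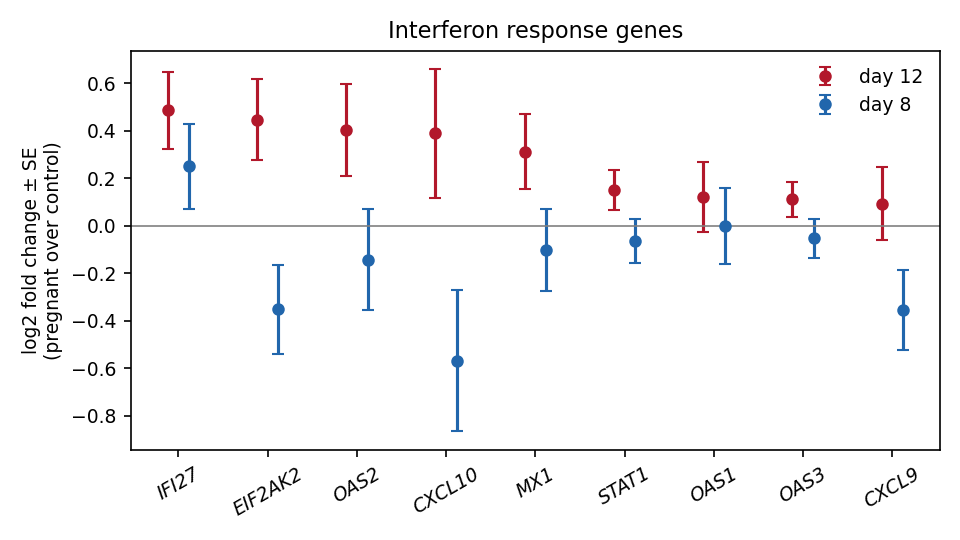
log2 fold change of pregnant over control (vertical axis, mean ± SE of the fit) for the 9 measured interferon response genes (horizontal axis) at day 12 (red, 6 mares) and day 8 (blue, 5 mares). At day 12 all 9 means lie above 0, and at day 8 the means of all but IFI27 lie below it.

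Growth factors and their binding proteins also rose as a list, with 6 of 7 measured members higher and a median of 0.30 (adjusted p = 0.0246; with an estimated correlation the adjusted p = 0.195, and with fry it was 0.0400). IGF2, a fetal and placental growth factor, was higher by 0.48 ± 0.21, MET, the receptor of hepatocyte growth factor, by 0.41 ± 0.14 and TGFB1 by 0.31 ± 0.13, and 0 members passed adjusted over the list alone. The list median on the 4 slides was 0.21, 0.48, 0.26 and 0.02. Secreted proteins of uterine fluid rose with 4 of 5 members higher and a median of 0.46 (adjusted p = 0.0246; with an estimated correlation the adjusted p = 0.225, and with fry it was 0.0405). TIMP1, an inhibitor of matrix metalloproteinases, was higher by 0.60 ± 0.15 and passed adjusted over the list alone, the retinol carrier RBP4 was higher by 0.59 ± 0.26 and the chaperone CLU by 0.46 ± 0.18. The list median on the 4 slides was 0.15, 0.54, 0.64 and -0.32, the last from mare 5 alone. With slide as the block the number of lists stayed at 3. With normexp background correction, which moved the median of all probes at day 12 to 0.33, no list passed, and relative to all probes the list medians became 0.05 for interferon response genes, -0.07 for growth factors and 0.07 for secreted proteins.

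The other 6 lists did not pass at day 12. Prostaglandin synthesis and signalling had 3 of 9 members higher and a median of -0.14 (adjusted p = 0.485). Within it PTGS2, the inducible cyclooxygenase, was higher by 0.27 ± 0.11 in 6 of 6 mares (adjusted p = 0.354), with its other 2 probes up to 1.03 (that one well above background on 4 of 6 pregnant and 3 of 6 control arrays), the prostaglandin F receptor PTGFR was lower at -0.49 ± 0.21 (adjusted p = 0.360), and 0 members passed adjusted over the list alone. Steroid metabolism had 8 of 11 members lower and a median of -0.04 (adjusted p = 0.196), and 2 passed adjusted over the list alone, namely HSD11B2, which inactivates cortisol, at -0.77 ± 0.23 and CYP17A1, a step of androgen synthesis, at -0.24 ± 0.07. The list probe of AKR1C1 stood at 0.04 ± 0.22, while another of its 3 probes, well above background on 3 of 6 pregnant and 4 of 6 control arrays, was lower in 6 of 6 mares (-1.61 ± 0.46, adjusted p = 0.182). The oestrogen receptor ESR1 stood at -0.18 ± 0.17 (adjusted p = 0.722). Extracellular matrix genes had 7 of 10 higher with a median of 0.14 (adjusted p = 0.420, with TIMP1 passing adjusted over the list alone), and chemokines with cytokines and their receptors had 11 of 17 higher with a median of 0.08 (adjusted p = 0.608). Calcium and ion transport genes had 4 of 5 lower with a median of -0.11 (adjusted p = 0.579). Markers of T and NK lymphocytes had a median of 0.04 over 5 members while the test leaned lower (adjusted p = 0.878), and 0 members of these last 3 lists passed adjusted over the list alone.

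Markers of other cell types had few named members at day 12. The smooth muscle marker TAGLN was higher by 0.90 ± 0.23 (adjusted p = 0.139 over all probes), the monocyte marker CD14 by 0.51 ± 0.16 (adjusted p = 0.214), and the platelet integrin ITGA2B was lower at -0.29 ± 0.08 (adjusted p = 0.158). Each passed adjusted over its list alone, which held 1, 4 and 2 measured members, so that for TAGLN there was no adjustment. The other members of the list of CD14, markers of macrophages and dendritic cells, were ITGAX (0.17 ± 0.22), LAPTM5 (0.08 ± 0.15) and CD68 (0.00 ± 0.15). The stromal markers DCN and LUM stood at 0.17 ± 0.13 and 0.09 ± 0.21, and the epithelial gene ESRP1 at 0.00 ± 0.08.

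At day 8 no named gene passed the test of pregnant against control. The smallest p among higher genes belonged to COPS9, a signalosome subunit (0.38 ± 0.10, SE, n = 5 mares, adjusted p = 0.745), the actin-severing protein gelsolin, GSN (0.56 ± 0.17, adjusted p = 0.813), PTGDS (0.23 ± 0.07, adjusted p = 0.823), PRKAG3 (0.31 ± 0.10) and SMIM7 (0.23 ± 0.08). Among lower genes they were C13H16orf90 (-0.56 ± 0.13, adjusted p = 0.725), the interstitial collagenase MMP1, SPI2 (-1.97 ± 0.53, well above background on 1 of 5 pregnant and 4 of 5 control arrays) and PAG (-0.49 ± 0.14). MMP1 was not well above background on any of the 5 pregnant arrays by this probe and was on 3 of 5 control arrays, a level at least 3.38-fold lower in pregnancy (adjusted p = 0.725), and its 8 probes ranged from -2.66 to -0.27. PTGS2 was lower in 5 of 5 mares (-0.37 ± 0.12, adjusted p = 0.833), ESR1 stood at 0.09 ± 0.19 and PTGFR at 0.24 ± 0.23.

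In limma's test 0 of 38457 probes passed at day 8, with a smallest adjusted p of 0.315. At an unadjusted p under 0.05 there were 2243, or 5.83%, where chance gives 1923, against 4797 or 12.5% at day 12.

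None of the 9 lists passed at day 8 by camera, with an estimated correlation or by fry, and 2 had an unadjusted p under 0.05. Interferon response genes were lower for 8 of 9 members with a median of -0.10 (adjusted p = 0.172), and chemokines with cytokines and their receptors for 11 of 17 with a median of -0.17 (adjusted p = 0.172). Mare 4 had the lowest median of both lists, -0.53 and -1.03, against -0.14 to 0.09 and -0.20 to 0.33 in the other mares. The medians were 0.14 for extracellular matrix genes (adjusted p = 0.314), 0.02 for growth factors, 0.10 for secreted proteins and -0.05 for calcium and ion transport (adjusted p = 0.718 each), 0.04 for steroid metabolism (adjusted p = 0.835), and 0.02 for prostaglandin genes and 0.06 for lymphocyte markers (adjusted p = 0.889 each). The mean over extracellular matrix genes was -0.03, and that over steroid metabolism genes -0.03, opposite to their medians. Adjusted over the list alone, 0 members of any of these lists passed at day 8. Without mare 2, 2 lists passed as lower.

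The pregnancy effect differed between the days for 2 transcripts. ENSECAT00000015626 had the higher effect at day 12 (adjusted p = 0.00286, n = 6 and 5 mares). Its fitted difference is no measured size, because it was well above background on no day 8 array and on only 1 of 6 control arrays of day 12. The change of ENSECAT00000022839 was lower at day 12 (difference -2.33 ± 0.28, adjusted p = 0.0434), with 3 of 6 pregnant arrays of day 12 well above background. In all 4 probes passed, 3 of them higher and 1 lower, against 5 and 0 with normexp, and none passed with quantile normalisation, without the mare block or in the authors' value table.

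No named gene passed the test of the difference. CHGA, higher in 6 of 6 mares at day 12, was lower in 5 of 5 at day 8 (-1.30 ± 0.53), a difference of 4.09 ± 0.72 (adjusted p = 0.146). PTGDS moved the other way, lower in 6 of 6 and higher in 5 of 5, a difference of -0.62 ± 0.10 (adjusted p = 0.107). PTGS2 was higher in 6 of 6 and lower in 5 of 5, a difference of 0.64 ± 0.17 (adjusted p = 0.258). GM2A was higher at day 8 in 5 of 5 mares by 0.48 ± 0.24 and differed between days by 1.61 ± 0.33 (adjusted p = 0.157). CHGA, PTGDS, PTGS2 and GM2A were picked for this comparison after their values were seen.

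Control arrays of day 12 differed from those of day 8 for many genes. The days also differ in slides, scan days and scanner software, so stage of the cycle and batch cannot be told apart. GM2A was higher at day 12 by 1.62 ± 0.27 log2 (SE, n = 6 and 5 mares, 3.08-fold, adjusted p = 0.00957), gelsolin (GSN) by 1.25 ± 0.24 (adjusted p = 0.0160), the nuclear receptor NR5A2 by 0.94 ± 0.26 (adjusted p = 0.0498), ANXA2, a calcium-dependent membrane-binding protein, by 0.90 ± 0.18 and the vascular growth factor VEGFA by 0.74 ± 0.20 (adjusted p = 0.0450). Lower at day 12 were gastrin, GAST (-3.10 ± 0.54, adjusted p = 0.0109), the synaptic vesicle protein SV2A (-2.73 ± 0.45, adjusted p = 0.00925), the Polycomb gene SUZ12 (-2.17 ± 0.55), the imprinted noncoding RNA H19 (-2.06 ± 0.42, adjusted p = 0.0194), the serotonin receptor HTR1B (-1.94 ± 0.43), the secreted phospholipase PLA2G2A (-1.87 ± 0.45) and TLR4, the receptor for bacterial lipopolysaccharide (-1.85 ± 0.47, adjusted p = 0.0387).

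**Figure D3:**
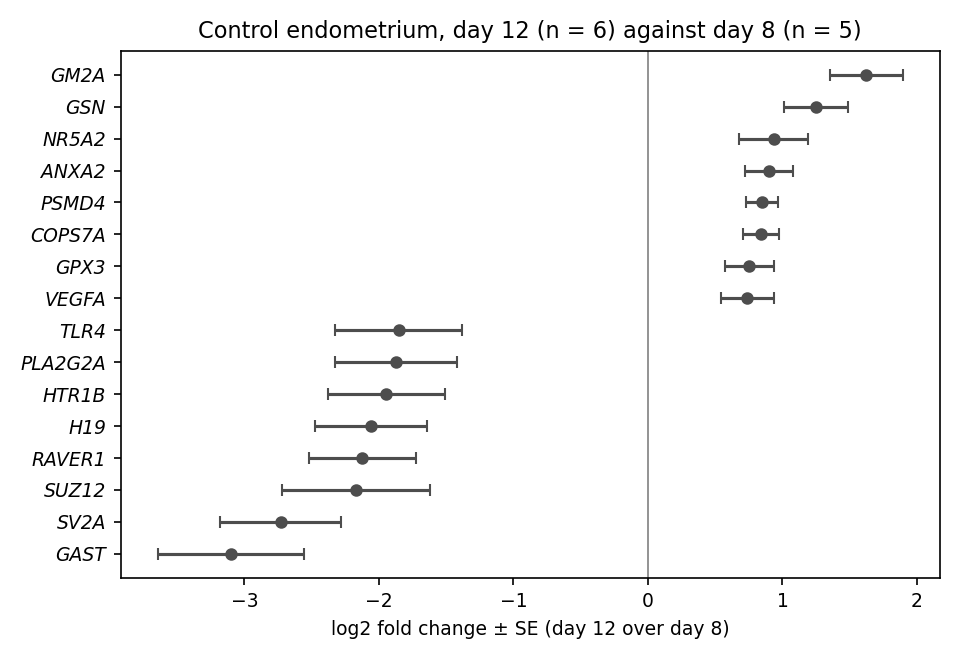
log2 fold change (horizontal axis, mean ± SE of the fit) of day 12 over day 8 in control endometrium (6 and 5 arrays) for the 16 genes that the naming rule took (vertical axis). It runs from -3.10 for GAST to 1.62 for GM2A. No slide or scan day held arrays of both days.

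The proteasome subunit PSMD4 (0.85 ± 0.12), the signalosome subunit COPS7A (0.84 ± 0.13) and the secreted glutathione peroxidase GPX3 (0.75 ± 0.18) were also higher, and the RNA-binding protein gene RAVER1 was lower (-2.12 ± 0.40). For VEGFA 1 of 10 probes passed. For ANXA2 1 of 3 passed and the probes ranged from -0.08 to 0.90, and for TLR4 1 of 2 passed and the other stood at 0.10. For H19 and NR5A2 1 of 2 passed each, and the other stood at -0.92 and 0.57, for GPX3 2 of 6 passed, for PLA2G2A 3 of 5 and for RAVER1 4 of 5. With 1 mare left out, NR5A2 and SUZ12 passed in 0 of 6 fits, VEGFA, GPX3 and TLR4 in 1, PLA2G2A in 2, ANXA2, H19 and HTR1B in 3, COPS7A in 4, GM2A, GSN and RAVER1 in 5, and GAST, SV2A and PSMD4 in 6. ESR1 was at -0.68 ± 0.25 (adjusted p = 0.114), PTGS2 at -0.96 ± 0.30 (adjusted p = 0.0728) and PTGFR at -0.13 ± 0.34, and none of these 3 passed.

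Of 609 named genes 66 passed between the control samples, 13 higher and 53 lower at day 12. Over all probes 2727 of 38460 passed, 950 higher and 1777 lower. Every slide and scan day held 1 day alone. With slide as a random block 772 passed, and with scan day as a random block, chosen after seeing the data, 211. With the authors' value table, over probes filled on every array and without further scaling, 11 higher and 271 lower passed. With the mare number as the block 0 were higher and 31 lower, so that none of the rises passed, nor did GAST, SV2A, SUZ12, RAVER1, H19, HTR1B, PLA2G2A or TLR4 among the falls, and the labels do not say whether a mare number is the same animal on both days.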

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

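The tests of mare 3's labels (including the division of probes at 4-fold) and of its arrays, of the number and spread of mares, of slide, of the lists in the splits that part all pairs, and of the lists' difference between days were chosen only after the results they bear on were seen.

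Interferon response genes differed between the days as a list, since the pregnancy effect was higher at day 12 than at day 8 (adjusted p = 0.00155 by camera over 9 lists, and adjusted p = 0.457 with an estimated correlation). At day 8 the list median was -0.53 in mare 4 and -0.14 to 0.09 in the other mares. At day 12 it was -0.20 in mare 3 and 0.16 to 0.42 in the other mares. In the test of the difference between days ENSECAT00000022839 differed by -2.33 log2, with 3 of 6 pregnant arrays of day 12 well above background. The fitted difference of ENSECAT00000015626 was 5.17, which is no measured size, since it was well above background on no day 8 array and on only 1 of 6 control arrays of day 12. In 100 splits of the 11 pairs into 6 and 5, 2 gave as many probes with a difference, the real one with 4 included, and the highest of the others gave 20. Few splits reached the real count. It fell to 0, however, with quantile normalisation, the filter on all 22 arrays, the authors' value table or no mare block. This count therefore does not exclude chance.

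A mare stood far from the others of its group in 4 of 96 sets of values, where about 5 would by chance. The imprinted RNA H19 had a level of 2.25 in the day 8 control sample of mare 1, against -0.36 to 0.30 in the other 4. Chemokines with cytokines and their receptors had a median change of 0.82 in mare 6 at day 12, against -0.22 to 0.13 in the others. Prostaglandin genes had a median change of -0.22 in mare 2 at day 8, against 0.06 to 0.15. The SD of all probes' changes was 0.593 in mare 3 at day 12, against 0.400 to 0.468.

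Without mare 3, 977 probes passed at day 12 instead of 102. An exchange of its pregnant and control labels is argued against by the 67 probes that changed over 4-fold in the other mares. Of these 49 moved the same way in mare 3, with a median signed change of 2.16. The 910 probes that changed less had a median of -0.25 in mare 3, against 0.53 to 0.76 in the others. The sign of that median is as an exchange would give, but 293 of the 910 moved the same way in mare 3, and an exchange would have to reverse both sets. The probes were selected by the fit of the other mares, so the values of those mares are no independent measure. Both arrays of mare 3 lay inside the range of the others in the share of spots well above background (0 outside), which argues against dim arrays. Another cell makeup of 1 biopsy cannot be told apart from other causes (exact binomial p = 0.556 over 2 marker lists, where the smallest possible is 0.111), and although 7 of 9 marker lists, most of them with 1 or 2 members, lay outside the other mares, from -1.82 for the ciliated to 3.65 for the neutrophil marker, mare 3 was at the extreme for 49.0% of all probes. The biological state of this mare stays open and untested.

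Of 98 splits of the day 12 arrays, 4 gave at least 102 probes, the real one included. These splits ignore the pairing by mare, and a pair left unparted adds nothing to the fitted effect, so this count cannot exclude chance. The highest of the others, with 1296, keeps the real labels in mares 1, 2, 4 and 6 and leaves mares 3 and 5 unparted. Among the 32 splits that part all 6 pairs, 2 gave as many, and chance cannot be excluded there, the other one exchanging only mare 3's labels with 996 probes, 482 higher and 514 lower. For the lists at day 12, 3 of 98 splits gave at least the real 3, the highest of the others also giving 3, which cannot exclude chance for the same reason. Of the 32 splits that part all 6 pairs 1 did, the real one, with 2 as the highest of the others. That count argues against chance for the lists as called with the preset correlation. It is, however, the lowest that these splits can give, and the test was chosen after the results were seen. With an estimated correlation or with normexp 0 lists passed.

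Probes passed at day 12 and 0 at day 8. The number of mares alone did not bring the count to 0, since with 1 mare number left out at least 22 probes passed at day 12. These fits also dropped the day 8 arrays of that number, where it had any. Most of them gave fewer than the 102 of the main fit, and the day 12 arrays alone gave 9. The test therefore does not show that the number of arrays is without effect. The changes did not spread more between mares at day 8, where their median SD was 0.846 of that at day 12. The fit shares 1 estimate of the spread over both days, however, and the median SE was 0.145 at day 8 against 0.133 at day 12. The ratio of the SDs therefore does not settle whether lower precision contributed to the count of 0. With a real count of 0 at day 8, all 100 of 100 splits gave as many by construction, for probes (highest other 158) and for lists (real 0, highest other 3), so these splits decide nothing. The stage of pregnancy stays open as an explanation, as do technical differences between the days, which cancel within pairs only in so far as they act on both arrays of a slide alike.

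Between the control samples of the 2 days 2727 probes passed, and 2 of 100 splits gave as many, the real one included. These splits treat the control arrays as interchangeable, although they were correlated within slides (0.259) and within scan days (0.349). This count therefore cannot exclude chance. The highest other split, with 4180 probes, set the day 12 controls of mares 2 and 5, which share a scan day, together with 4 of the 5 day 8 controls, and it does not follow scan day, since it divides the 2 day 8 controls of 1 scan day. With slide as a random block 772 probes passed, which bounds only the variation between slides of the same day, and with scan day 211. The days cannot be told apart from their slides, scan days and scanner software, so stage of the cycle and batch both stay open.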

How the results depend on the processing

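The fit with scan day as a random block was chosen after seeing the data, and all other alternatives were planned. No named gene that passed changed direction in any alternative. At day 12, 8 genes gave 62 values past the threshold and 63 that were not, out of 125. GM2A passed in 8 of 10 settings and without any 1 of the 6 mares, CHGA in 5 of 9 and in 2 of 6 fits with 1 mare left out, ABCC1 in 5 of 10 and 2 of 6, ANGPTL2 in 6 of 10 and 3 of 6, CDH13 and RND3 each in 6 of 10 and 1 of 6, CALCA in 4 of 8 and 1 of 6 (change from 0.95 to 2.60), and PTGDS in 5 of 10 and 1 of 6. Between control samples NR5A2 passed in 4 of 11 settings and 0 of 6 fits with 1 mare left out (change down to 0.24), VEGFA in 4 of 11 and 1 of 6 (down to 0.17), and SUZ12 in 8 of 11 and 0 of 6. The 102 probes of day 12 became 13 with normexp, 218 with a filter on all 22 arrays, 303 with the authors' value table, 287 with the trended robust prior and 9 with the day 12 arrays alone, while without a replicate block, that is without the pairing by mare, 41 passed. With 1 mare left out the count ran from 22 to 977 (22 without mare 1, 31 without mare 2, 977 without mare 3, 47 without mare 4 and 28 without mare 6). The count of 0 at day 8 was 0 in every alternative. The 4 probes of the difference between days became 11 with the robust prior, 2 without a filter or with slide as a block, and 0 with quantile normalisation, the filter on all 22 arrays, the authors' value table or no replicate block, and 0 to 33 with 1 mare left out (33 without mare 3, 2 without mare 4, 0 without mares 1, 5 or 6). The 3 lists at day 12 became 0 with normexp or an estimated correlation and 2 to 3 with 1 mare left out, of which the 3 without mare 4 were 2 higher and 1 lower, while the day 12 arrays alone gave 3 higher and 1 lower, as did the mean of all probes of a gene, and the 0 lists at day 8 became 0 to 2 (2 without mare 2). The 2727 probes between control samples became 1630 with normexp, 4504 with quantile normalisation, 282 with the authors' value table (3.90% higher instead of 34.8%), 5545 with all 22 arrays, 772 with slide and 211 with scan day as a random block, 31 with the mare number as a replicate block (0 higher and 31 lower), and 347 to 2046 with 1 mare left out (1112 without mare 1, 1775 without mare 3, 347 without mare 4, 450 without mare 5 and 621 without mare 6). The block by mare changed no call at day 8 and no count of lists. Fewer arrays enter where 1 day is fitted alone or a mare is left out. Leaving a mare out removed its number on both days, but mare 3 at day 12 only. The cause of the other changes was not tested. Signal over background limits dim probes such as CALCA, which was well above background on 1 of 6 control arrays at day 12.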

Other observations

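The test of the day 12 changes at day 8 was written before its result was seen. The levels of single transcripts were chosen for description after their values were seen.

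DN508408, a transcript without a symbol that rose at day 12, also differed between control samples of the 2 days, which were on different slides and scan days. Its mean level was 2.30 ± 0.88 in pregnant and -4.42 ± 1.33 in control samples of day 12 (SD, n = 6 each), and it was not well above background on any of the 5 day 8 control arrays, so that control endometrium of day 12 exceeded that of day 8 at least 11.5-fold (adjusted p = 0.00438). At day 8 it was well above background on 2 of 5 pregnant arrays, with a change between -1.04 and 3.45 log2 per mare (adjusted p = 0.848). DN510735, which fell at day 12, stood at -0.56 ± 0.67 in pregnant and 1.76 ± 1.11 in control samples of day 12, and at 3.01 ± 0.28 and 2.73 ± 0.65 at day 8 (n = 5 each).

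Lists with fewer than 5 measured members had no list test. All 4 measured mucin, integrin and adhesion genes were higher at day 12, led by the hyaluronan receptor CD44 (0.43 ± 0.19, adjusted p = 0.373) and the integrin chain ITGA5 (0.38 ± 0.21), and 0 of them passed adjusted over the list alone. The endothelial adhesion gene PECAM1 was at 0.44 ± 0.16 (adjusted p = 0.305) and passed adjusted over its list of 2. All 3 measured genes of antigen presentation were higher, with CD74 at 0.25 ± 0.19 and B2M at 0.04 ± 0.16, and 0 passed adjusted over the list alone. Of 4 measured Wnt genes 2 were higher and 2 lower with a median of 0.03, from -0.14 ± 0.17 for WNT2 to 0.47 ± 0.27 for RSPO3. The sugar transporter genes SLC5A1, SLC2A4 and SLC2A5 were at -0.25 ± 0.23, 0.07 ± 0.10 and 0.08 ± 0.20, and 0 members of either list were past the threshold.

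A hypothesis was that the changes of day 12 had begun by day 8. Over the 62 accessions past the threshold at day 12, the day 8 change signed by the day 12 direction had a mean of -0.06 ± 0.16 (SD, n = 5 mares), and 27 of 62 had the same sign as at day 12. The exact one-sided sign-flip p was 0.781, where the smallest possible is 0.0312, so the test gave no evidence of an earlier start.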
